A study of Mus musculus with 24 samples.

How the data were processed

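Poly(A) 3' tag RNA sequencing was made from mouse embryonic stem cells in 4 lines and 2 states, with 3 samples per group in the labels, 24 in all. The lines were wild type, MLL3KO_MLL4fl (called the floxed line here), MLL3KO_MLL4KO (the knockout line) and MLL3CD_MLL4CD (the catalytic-dead line). MLL3 and MLL4, encoded by Kmt2c and Kmt2d, are histone H3 lysine 4 methyltransferases that act at enhancers. Wild-type and catalytic-dead cells are of the R1 line per the labels, and the floxed line was taken as the parent of the knockout line. The floxed line lacks MLL3 by its name, so its comparison with wild type joined the loss of MLL3 with any difference between lines. Each genotype had its own line, so catalytic-dead against wild type and knockout against floxed may also include other differences between lines. Naive cells were grown in LIF and 2 inhibitors, and formative cells were collected 63 h after their withdrawal, per the labels. Replicates were cultured independently per the series' design text.

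Per the labels' protocols, RNA was extracted with Trizol and 200 ng of total RNA went into a QuantSeq 3' FWD library, read single-end for 50 bases on an Illumina instrument. The labels state at least 10 M (mega) mapped reads per sample. Per the submitters' processing notes, reads were checked with FastQC 0.11.8 and MultiQC, trimmed with cutadapt 2.5, aligned to mm10 with STAR, counted with featureCounts of Subread 1.6.4, and normalised with DESeq2 1.34.0 named as the package. The strand setting of the counting is not given in the sources used here, so values of overlapping, antisense, paralogous and pseudogene models are uncertain.

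The deposited table held 16617 genes in 8 columns, one per group, with 9 decimals. Its values were checked to be log2 CPM (counts scaled to a common library total), with a prior count of 2 scaled to library size, averaged by the authors over the libraries of a group. Back-transformed columns summed to 984624 to 998847. A symbol was missing for 2574 genes. Identifiers were matched to GENCODE vM21 (GRCm38, the build also called mm10) for 16606 genes, 8 had no symbol from either source, and 7 symbols occurred more than once. The column named for the conditional line was read as the floxed line.

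Library counts were recovered from the averages, since each average fixes the whole counts that can produce it. The library sizes solved from the table lay within 0.042 of whole numbers. The sizes of 23 libraries were found, from 4.81 to 15.4 M counts, of a total of 234513119 and a mean of 9771380 over 24 libraries. The naive wild-type column averaged 2 libraries, and 6812462 counts were left for a library in no column. The formative knockout column averaged 4 libraries, of which 1, with 6919314 counts, also entered the formative catalytic-dead column. It was removed from the formative knockout mean, and where its own value for a gene was not recovered the formative catalytic-dead mean took its place, an approximation. At least 99.81% of genes with up to 100 counts were recovered in each group, as were 10177 genes (61.2%) in all groups. Abundant genes have too many possible counts, so they have deposited means but no library values, and are given here as values without a test. The search window of 1.0 log2 and the limit of 0.3 solutions expected by chance were set after the yield had been seen. Libraries are called a, b and c in order of falling depth.

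The procedure was tested on simulated data for 23 libraries with a log2 SD of 0.2 between replicates. Every gene had this SD. In the real libraries the 95th percentile over recovered genes of 100 counts or more was 0.402 to 0.746 per group. The simulation therefore does not cover the most variable genes, for recovery or for calls. All 23 library sizes and every recovered count were right in this setting. In a simulated naive knockout comparison with 200 changed genes, 68 genes were called, of which 4 (5.9%) were unchanged. The test called 5 of 44 genes changed by 1.5-fold (11.4%), 28 of 49 changed by 2-fold (57.1%) and 31 of 31 changed by 4-fold (100.0%), with median sizes of 0.57, 0.92 and 1.85 log2. The prior count therefore understates changes of low genes. Without weights 70 genes were called, of which 10 were unchanged, and weights were added after that result and after the unweighted results of the study had been seen.

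Differences were tested with limma 3.58.1 in R 4.3.3 on the recovered log2 CPM values, in 1 linear model of the 8 groups. Weights per gene and group came from a lowess trend (span 0.3) of the SD on the mean count, and variances were moderated with a trend. Genes needed, in at least 3 libraries, a CPM equal to 10 counts at the median library size (16596 of 16617). Values that were not recovered counted as passing, also in the stricter filter below. Past the threshold means a Benjamini-Hochberg adjusted p under 0.05 over all tested genes of a comparison, and rose and fell are used only for such genes. Said of a list, these words mean that its camera test, described below, passed in that direction, whatever the count of members past the threshold. A gene was tested where library values were recovered in every group of the comparison. Errors given as SE belong to log2 differences of this model, and SDs are between recovered libraries, with n = 3 except n = 2 for naive wild type. The contrasts were 4 transitions (formative minus naive), knockout minus floxed, catalytic-dead minus wild type and floxed minus wild type in each state, 2 differences of transitions and 2 differences of effects, 14 in all. The planned count model could not be fitted to the deposited values because they are log2 means, and it was not run on the recovered counts.

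The 27 gene lists were fixed before the data were examined, as were the groups, contrasts, filter, thresholds and the rule for naming genes. The lists cover naive, formative and shared pluripotency, 2-cell-like, germline, primitive endoderm, mesendoderm, neuroectoderm, trophoblast and fibroblast genes, H3K4 methyltransferase complexes, other chromatin regulators, DNA methylation, FGF and ERK, LIF and STAT3, Wnt, Nodal, p53 and interferon responses, glycolysis, oxidative phosphorylation, cholesterol biosynthesis, proliferation, imprinted genes, Hox genes, Y-linked genes with Xist, and mitochondrial transcripts. Of these, 1 list (mitochondrial transcripts) had no member in the table. Some genes are in more than 1 list, such as Lef1 and the de novo DNA methyltransferases. List tests used camera of limma with a preset correlation of 0.01 on genes recovered in every library, for the 14 lists with at least 3 such genes. The other 12 lists had too few, and only their values are given. Camera covered 5 of 20 imprinted, 6 of 13 FGF and ERK, 5 of 21 glycolysis and 17 of 20 Hox genes. A camera p can therefore rest on fewer genes than the count of tested genes beside it. List medians are over all members in the table. List medians were also set against 10000 random lists matched in 20 bins of expression. Of 196 camera tests, 47 passed the threshold, and 30 did so with an estimated correlation. Counts of genes adjusted over the list alone are given beside counts over all genes.

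The naming rule took Kmt2c and Kmt2d in every group, then per comparison the genes with the largest changes past the threshold, a mean of at least 10 CPM in a group and no overlap between libraries (6 per direction, 4 for differences, 3 for floxed against wild type and the transitions outside wild type), then up to 4 changed and 2 abundant members per list. Models without a name were left out, and so were genes with no more than 3 counts in a group. Values in the report are log2 differences of CPM with the prior count unless another unit is given, and intervals and floors cover counting error only. A list median given with the floor leaves out genes with no more than 3 counts in both groups and sets a group at 0 to 3 counts over the group.

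The alternatives chosen before the data were examined were no filter, a stricter filter of 2 CPM in 3 libraries (14474 genes), size factors in place of library totals, an estimated correlation, each library left out, the groups of a contrast alone, and sets at a larger change. Added after the data were seen were genes recovered in every library, the formative knockout column as deposited, a prior count of 0.5, voom weights and no weights. The test of genes changed in opposite directions was also added after the overlaps were seen. Size factors came from 7200 genes. Random splits numbered 10 for 3 against 3 libraries and 100 drawn for differences. Recovery and summaries used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, statsmodels 0.14.6 and numba 0.67.0, figures used matplotlib 3.10.9, and R read JSON with jsonlite 2.0.0.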

Results

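The recovered libraries held 8839216 and 14237630 counts in naive wild-type cells and 7527501 to 13883231 in formative wild-type cells. Totals ran from 6619593 to 10734725 in naive floxed, 10717398 to 13095346 in formative floxed, 8080680 to 15425959 in naive knockout, 4808564 to 9975146 in formative knockout, 6095600 to 8945300 in naive catalytic-dead and 6919314 to 13973647 in formative catalytic-dead cells. All 23 libraries correlated best with a library of their own group. Counts were searched only in a window around each group mean, which can raise the likeness of libraries within a group. The median correlation across genes was 0.891 within groups and 0.607 between them. The median SD of a gene between libraries was 0.171 to 0.271 log2 per group. Where 1 of the 2 naive wild-type libraries was left out, 1 remained, and it was assumed to vary like the libraries of the other groups.

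The targeted genes came first. Kmt2c (MLL3, chromosome 5, 25271798 to 25498783 of GRCm38) stood at 48.8 CPM in naive and 37.1 CPM in formative wild-type cells. It stood at 23.4 and 19.2 CPM in the floxed line, 22.0 and 15.7 CPM in the knockout line and 67.4 and 35.4 CPM in the catalytic-dead line. The log2 SD was 0.52 in naive wild-type (n = 2) and 0.69 in naive floxed cells (n = 3). Kmt2c was lower by -1.06 in naive floxed than wild-type cells (adjusted p = 0.0395), a call lost without naive floxed library b (-0.66, adjusted p = 0.148), without naive wild-type library a (-0.70, adjusted p = 0.361), without weights (adjusted p = 0.0537) and with the groups of the contrast alone (adjusted p = 0.328). Kmt2d (MLL4, chromosome 15, 98831669 to 98871204) stood at 29.0 and 35.7 CPM in naive and formative wild-type cells and at 28.8 and 25.5 CPM in the floxed line. It stood at 17.6 and 20.2 CPM in the knockout and at 27.6 and 20.3 CPM in the catalytic-dead line. Kmt2d fell by 0.71 in naive knockout against floxed cells (adjusted p = 0.00653, but 0.0519 with the groups of the contrast alone) and by 0.81 in formative catalytic-dead against wild-type cells (adjusted p = 0.00398). It did not pass in formative knockout (-0.34, adjusted p = 0.257) or naive catalytic-dead cells (-0.07, adjusted p = 0.877). In formative floxed against wild-type cells it was lower by -0.49 (adjusted p = 0.0764), and passed without formative wild-type library b (-0.61, adjusted p = 0.0437; 0.0423 to 0.299 over all alternatives). The tags lie at the 3' end of a transcript, so these values test neither the deletions nor the catalytic changes.

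Wild-type cells exchanged naive for formative genes over 63 h. Fgf8, a growth factor of the early embryo (chromosome 19, 45736798 to 45742915), rose from 0.514 to 34.8 CPM, by 6.08 log2 (SE 0.54, adjusted p = 2.85e-09, 3 against 2 libraries). Ly6a, a surface antigen, fell by 5.82 (SE 0.39, adjusted p = 3.17e-11), from 43.9 to 0.775 CPM, and Trpm1, an ion channel, fell by 5.55. The naive factor Esrrb was too abundant for a test and stood at 388 CPM in naive and 24.7 CPM in formative cells. Of 11823 tested genes 2250 rose and 1485 fell, and a further 441 untested genes were at least 2-fold higher and 181 at least 2-fold lower. Against size factors the median of all genes shifted by -0.15 here, by -0.16 in the floxed, by -0.28 in the knockout transition, and by -0.15 in naive catalytic-dead against wild-type cells.

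Of the 18 naive pluripotency genes 16 had values at least 2-fold lower in formative wild-type cells. Of the 11 tested, 10 fell over all genes and 10 when adjusted over the list alone, among them Tcl1, a coactivator of AKT (-3.64), Mras (-3.46) and Jam2 (-2.84). Of the 17 formative genes 15 were at least 2-fold higher. The 4 that rose of 5 tested (4 adjusted over the list alone) included the transcription factors Grhl2 (4.02), Sox4 (3.08) and Lef1 (2.56). Untested values were higher by 6.09 for the growth factor Fgf5, 3.72 for Dnmt3b and 2.64 for Dnmt3a. Mesendoderm genes rose as a list (camera adjusted p = 0.0132), with 5 of 9 tested genes up, 1 down and 6 passing when adjusted over the list alone, led by the signal Wnt3 (4.94) and the transcription factors Evx1 (2.03) and Eomes (1.63, SE 0.30). A list call printed with 1 adjusted p also passed with an estimated correlation. FGF and ERK response genes rose (median 0.94, adjusted p = 0.0123), including Egr1 (4.48, or 5.07 without naive wild-type library a) and the phosphatase Dusp4 (3.53). In this list 4 of 8 tested genes rose (5 adjusted over the list alone), and 2 did without naive wild-type library a. Imprinted genes rose (median 1.10, adjusted p = 0.0132), with 7 of 10 up and 1 down (9 adjusted over the list alone), including the growth inhibitor Cdkn1c (3.26) and Dlk1 (2.81). The 2-cell-like list rose (median 1.29, adjusted p = 0.0123), with 7 of 9 tested genes up (8 adjusted over the list alone) but 3 without naive wild-type library a.

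Other lists had members on both sides. LIF and STAT3 response genes had a median of -0.74, with 5 of 7 tested genes down and 1 up (6 adjusted over the list alone). Socs3, a feedback inhibitor, fell by 2.66, Stat3 by 2.31 and the receptor Lifr by 2.13, while Gadd45g rose by 2.10. Fibroblast genes had a median of 2.04, with 6 of 8 up and 1 down (8 adjusted over the list alone), but camera did not pass (adjusted p = 0.17). Among trophoblast genes, 4 of 10 rose and 2 fell, with 2 rising without naive wild-type library a. Krt18, an epithelial keratin, rose by 2.64, and the transcription factors Tfap2c (-2.49) and Tead4 (-2.47) fell. Among germline genes 5 of 15 rose and 4 fell (9 adjusted over the list alone), with 3 rising without naive wild-type library a, and the piRNA pathway gene Mael rose by 3.30. The neuroectoderm list had 4 of 10 up and 1 down (camera adjusted p = 0.0773), with the eye and neural factor Pax6 at 2.04. The antiviral genes Oas1a (-4.68) and Ddx58 (-3.10) fell. The Wnt list had a median of 0.65 and a mean of 0.12 while camera pointed down (adjusted p = 0.487), and the DNA methylation list had a median of -0.41 and a mean of 0.39.

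The other lines made much of this change. In the floxed line 2431 of 11063 tested genes rose and 1244 fell, in the knockout line 2249 of 10878 rose and 570 fell, and in the catalytic-dead line 2098 of 11565 rose and 1218 fell. In the knockout transition 79.8% of changed genes were higher, but 63.3% with size factors. The naive list had medians of -2.50, -1.94 and -2.52 in the floxed, knockout and catalytic-dead lines, and the formative list 2.16, 2.71 and 2.27. Fgf8 rose by 5.18 in the floxed line (adjusted p = 2.19e-09) and by 4.41 in the catalytic-dead line (adjusted p = 3.69e-08). In the knockout line it went from 0.329 to 0.821 CPM, a difference of 1.32 that did not pass (adjusted p = 0.117). It passed there with the formative column as deposited (2.28). Fgf5, another growth factor of formative cells, had untested values higher by 6.22 in the knockout line and rose by 4.41 in the floxed and 4.27 in the catalytic-dead line. Eomes, a T-box factor of mesendoderm, fell in the floxed (-1.48, adjusted p = 3.38e-04) and catalytic-dead lines (-2.35, adjusted p = 3.29e-06) and rose in the knockout line (1.91, adjusted p = 1.25e-03).

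In the knockout transition all 7 tested FGF and ERK genes rose (7 adjusted over the list alone, median 2.13, camera adjusted p = 1.51e-06), including Spry4, an inhibitor of receptor signalling (5.62, SE 0.55), and Egr1 (4.83). Neuroectoderm genes rose (adjusted p = 0.000704), with 6 of 9 up (7 adjusted over the list alone), including the factors Zic1 (4.19) and Pax6 (1.73). Mesendoderm genes fell as a list (adjusted p = 0.00758; 4 of 9 down and 1 up, 5 adjusted over the list alone), as did Wnt genes (adjusted p = 0.00129; 5 of 11 down and 1 up, 7 adjusted over the list alone), among them the Wnt inhibitor Dkk1 (-4.32), the target Sp5 (-1.47) and Wnt3 (-1.22). Fibroblast and imprinted genes rose with camera (adjusted p = 0.0376 for both) but not with an estimated correlation (adjusted p = 0.0654). The fibroblast call was lost without naive knockout library c (adjusted p = 0.0757) or formative knockout library a (0.071), and the imprinted call without formative knockout library a (0.0591) or c (0.051). Of these 6 lists, FGF and ERK alone passed in the camera test of the difference from the floxed transition (adjusted p = 0.00294), and the others had adjusted p of 0.477 to 0.809. In the catalytic-dead line neuroectoderm genes rose (7 of 11, 7 adjusted over the list alone, adjusted p = 0.0105, with an estimated correlation 0.0681), including Pax6 (3.60, or 3.01 without naive catalytic-dead library a). Wnt genes fell there (5 of 12 down and 2 up, 10 adjusted over the list alone, adjusted p = 0.00881, with an estimated correlation 0.103), including Axin2 (-2.28) and Sp5 (-2.22), while Lef1 rose by 4.55. In the floxed transition the lowest camera adjusted p was 0.131, shared by the fibroblast and neuroectoderm lists (up) and the Wnt list (down), and Wnt3 rose by 2.89 while Sp5 fell by 2.06 and Evx1 by 2.66 (-3.37 without formative floxed library b).

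The size of the transition was then compared between lines on gene sets taken from a line outside the comparison. Of 856 genes repressed in wild-type cells, the change was smaller in knockout than floxed cells for 184 past the threshold and larger for 7. The median of these tested genes was -1.18 in the floxed and -0.33 in the knockout line. Over all 1603 repressed genes, tested or not, it was -1.11 and -0.41 (-1.28 and -0.69 with size factors), and over the 262 with a mean of at least 32 CPM it was -1.33 and -0.73 (-1.49 and -1.01). Of 1720 induced genes it was smaller for 169 and larger for 51, with medians of 1.69 and 1.28. Over all 2969 induced genes these were 1.45 and 1.13 (1.29 and 0.85 with size factors). The repressed genes differed mainly in naive cells, where their median knockout effect was -0.66, against 0.12 in formative cells. There 301 were lower and 50 higher than in floxed cells in the naive state. The induced genes had median knockout effects of 0.18 in naive and -0.10 in formative cells. For the catalytic-dead line, with sets from the floxed line, the change was smaller for 45 and larger for 6 of 814 repressed genes, and smaller for 56 and larger for 18 of 1895 induced genes. The 45 became 28 without formative wild-type library a, and the 56 became 16 without naive wild-type library a and 26 without naive wild-type library b. The differences of transitions passed for 829 genes in the knockout comparison (522 up, 307 down) and for 331 in the catalytic-dead comparison (189 up, 142 down). The 331 became 164 without naive wild-type library a and 219 without naive catalytic-dead library c. FGF and ERK genes gained in the knockout difference (median 1.78, camera adjusted p = 0.00294), with 3 of 6 tested genes up (4 adjusted over the list alone). The 3 became 1 without formative floxed library a, naive floxed library a or naive floxed library c.

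**Figure D1:**
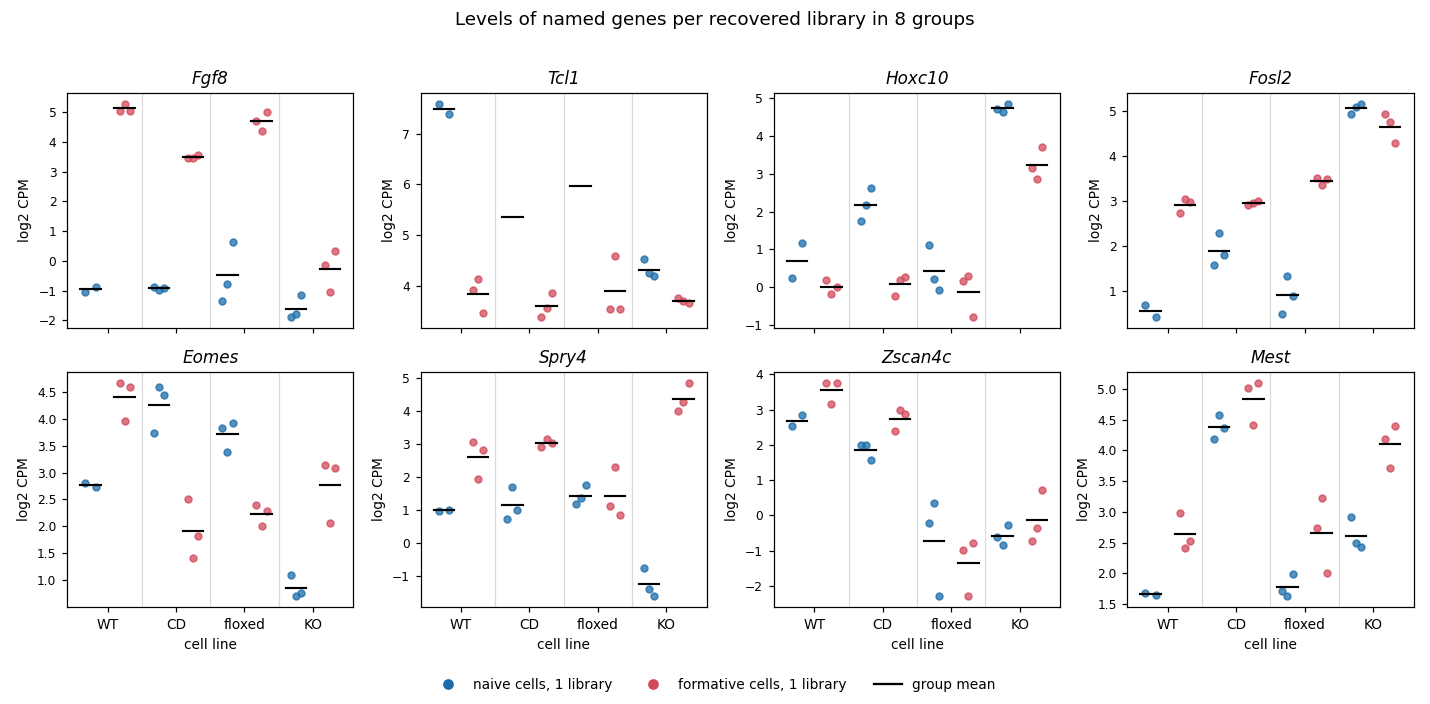
Log2 CPM of 8 genes in the recovered libraries of each line (points) with the mean of each group (black bars), naive in blue and formative in red; a bar without points is an abundant gene without library values. Fgf8 reached 34.8 CPM in formative wild-type, 25.7 CPM in formative floxed and 11.2 CPM in formative catalytic-dead cells, and 0.821 CPM in formative knockout cells.

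Hox genes rose as a list in naive knockout against floxed cells. Hoxc10 (chromosome 15, 102966796 to 102971893), a body patterning factor, rose to 26.5 CPM (4.30 log2, SE 0.36, adjusted p = 6.15e-09, 3 against 3 libraries). Tex13b, a testis gene, rose by 5.06 (SE 0.49), the oocyte gene Nlrp4c by 4.92 and the AP-1 subunit Fosl2 by 4.16. Gpa33, an epithelial antigen, fell by 4.62 (SE 0.46), and the hormone gene Calca (-4.12) and Enox1 (-4.43) fell too. Of 11362 tested genes 898 rose and 1063 fell, and of the untested, 174 were at least 2-fold higher and 184 at least 2-fold lower. The untested Hoxa9 was higher by 6.82 (0.511 against 57.7 CPM), and the DNA methyltransferase cofactor Dnmt3l was lower by -4.25. Of 17 tested Hox genes 5 rose (5 adjusted over the list alone, median 0.89, or 0.99 with the floor, camera adjusted p = 0.000478), including Hoxc8 (3.64), Hoxc6 (3.02), Hoxa7 (2.77) and Hoxb9 (2.33).

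Naive pluripotency values were lower in naive knockout cells, with a median of -0.46. Tcl1 was lower by -1.64 and Esrrb by -0.55, untested, while Nanog was higher by 0.35. The 2-cell-like list had a median of 0.00 and a mean of -0.13. Among formative genes Sox4 rose (2.15) and Sox3 (-2.36) and Foxd3 (-1.72) fell, the 3 of 13 past the threshold (6 adjusted over the list alone, median -0.33, or -0.36 with the floor). The untested Dnmt3b and Dnmt3a were lower by -1.64 and -1.30, and the DNA methylation list had a median of -1.09. Gbx2, a homeobox factor of naive cells, fell by 1.65. FGF and ERK genes had a median of -0.78 (camera adjusted p = 0.263). Spry4 fell by 2.69 (adjusted p = 0.00191) and the phosphatase Dusp6 by 1.38, Phlda1 rose by 0.77, and these were the 3 of 9 past the threshold (4 adjusted over the list alone).

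Lineage genes moved in both directions in naive knockout cells. The primitive endoderm list rose with camera (adjusted p = 0.0169), with a mean of 0.48 and a median of -0.09; the adaptor Dab2 (3.30, SE 0.33) and the collagens Col4a2 (2.59) and Col4a1 (1.70) rose, and 1 of the 10 tested fell (5 adjusted over the list alone). Among mesendoderm genes Wnt3 (3.63, SE 0.43), Foxa2 (2.75) and Sp5 (1.37) rose and Eomes fell by 2.85 (SE 0.40, adjusted p = 5.99e-06), from 13.1 to 1.81 CPM, the 4 of 9 past the threshold (4 adjusted over the list alone, median 0.05). Trophoblast genes rose (camera adjusted p = 0.0226, with an estimated correlation 0.0512), with 4 of 7 up and 1 down (6 adjusted over the list alone), including Krt7 (2.24) and Cdx2 (2.73, or 2.06 without naive floxed library c), while Ascl2 fell by 1.42. Neuroectoderm genes rose (median 0.86, adjusted p = 0.0487, with an estimated correlation 0.0834), a call lost without naive floxed library b (0.124) or c (0.0818) or naive knockout library a (0.0704) or b (0.0516). In that list 4 of 10 rose, including Sox1 (0.92), but 2 without naive knockout library a or naive floxed library b or c. Wnt genes rose (5 of 12 up and 1 down, 6 adjusted over the list alone, adjusted p = 0.035, with an estimated correlation 0.145, and 0.302 without naive floxed library b), with Dkk1 at 4.69 (3.96 without naive floxed library c) and Cdx1 at -2.14. The imprinted list was higher with camera on 5 genes (adjusted p = 0.0297, with an estimated correlation 0.0729, and 0.124 without naive floxed library b). Of 8 tested imprinted genes 2 rose (3 adjusted over the list alone, median 0.50 over the list), including Dlk1 (2.75) and Ndn (1.73), and the untested Peg10 was higher by 4.23. Germline genes had a median of 0.46, with 5 of 16 up and 3 down (10 adjusted over the list alone). The nucleotide carrier Slc25a31 rose by 2.53, and the RNA-binding factor Dazl fell by 2.63. Fibroblast genes had a median of 0.76, above 99.4% of random lists matched for expression, but 1 of 7 up and 1 down (3 adjusted over the list alone) and no camera call (adjusted p = 0.97), with the untested smooth-muscle actin Acta2 higher by 3.53.

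In formative cells Hox genes rose and Fgf8 fell in knockout against floxed cells. Fgf8 fell by 4.97 (SE 0.45, adjusted p = 4.42e-09), from 25.7 CPM in floxed to 0.821 CPM in knockout cells, and Trim67, a neuronal ubiquitin ligase, fell by 4.65. Col8a1, a collagen, rose by 6.02 (SE 0.44, adjusted p = 1.65e-10), the annexin Anxa1 by 5.91 and Tex13b by 5.26. Of 10956 tested genes 1155 rose and 722 fell, and 215 untested genes were at least 2-fold higher and 136 at least 2-fold lower. Of 20 tested Hox genes 15 rose and 1 fell (17 adjusted over the list alone, median 1.98, camera adjusted p = 7.6e-08), including Hoxa9 (4.74, from 0.892 to 23.8 CPM), Hoxa5 (3.77) and Hoxa10 (4.04, or 4.70 without formative floxed library b). Hoxc8 rose by 3.60, a call lost with the formative knockout column as deposited (2.46). A difference of the Hox list between the formative and naive knockout effects did not pass (camera adjusted p = 0.477). FGF and ERK genes rose (median 0.55, adjusted p = 0.000252), with 4 of 6 up (5 adjusted over the list alone) but 2 without formative floxed library a. Spry4 rose by 2.95 (SE 0.33, adjusted p = 1.97e-07), from 2.69 to 20.7 CPM, and the untested Phlda1 was higher by 1.99. Neuroectoderm genes rose (5 of 9 up and 1 down, 6 adjusted over the list alone, median 1.05, adjusted p = 0.00304), including Zic1 (3.51, SE 0.31), while the neural repressor Hes5 fell by 2.43. Imprinted genes rose (4 of 7, median 0.72, adjusted p = 0.00036), including Sgce (2.42), Dlk1 (1.04) and the untested Peg10, higher by 2.94.

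Nodal pathway values were lower in formative knockout cells, with a median of -1.03 over 8 abundant genes without a test. The antagonist Lefty1 was lower by -3.87, Nodal by -1.53 and its coreceptor Tdgf1 by -1.08. Formative pluripotency genes had a median of 0.82, with 3 of 4 tested up, including Fgf15 (1.68), and untested values higher by 2.76 for Lef1 and 1.53 for Fgf5. Naive genes had a median of 0.27, with the nuclear receptor Nr0b1 up (2.13) and Dppa3 down (-1.71) among 7 tested. Primitive endoderm genes had 3 of 9 up and 2 down (8 adjusted over the list alone), including Col4a1 (1.78), Col4a2 (1.72) and Amn (-1.69). Mesendoderm genes had 2 up and 2 down of 9 (median -0.48, camera adjusted p = 0.62), with Sp5 at 1.96. Germline genes had 5 of 15 up and 3 down (9 adjusted over the list alone), with 3 up without formative knockout library a or b and 1 down without library a, and Mael fell by 2.41. Fibroblast genes had a median of 1.15, with 3 of 6 up and 2 down (5 adjusted over the list alone, camera adjusted p = 0.94), including the collagen Col1a2 (2.71), the mesenchymal factor Twist1 (1.43) and the proteoglycan Dcn (-2.42). LIF and STAT3 genes had 3 of 5 up (4 adjusted over the list alone), with Gadd45g at 2.77 and Lifr at 1.11. The 2-cell-like list had a median of 0.45 (0.71 with the floor), trophoblast genes 3 of 9 up, and Wnt genes 2 of 11 up (camera adjusted p = 0.174).

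In naive catalytic-dead cells, in which both proteins lack activity by the line's name, imprinted genes rose as a list against wild-type cells. Protein levels were not measured here. Sox9, a transcription factor, rose by 4.58 (SE 0.56, adjusted p = 4.22e-06, 3 against 2 libraries), Dab2 by 3.84 (SE 0.33, adjusted p = 1.14e-08) and Acta2 by 2.83. The apolipoprotein gene Apol6 fell by 4.84 (SE 0.43), Ly6a by 4.26, from 43.9 to 2.29 CPM, and Oas1a by 3.92. Of 12750 tested genes 750 rose and 581 fell, with 123 untested at least 2-fold higher and 52 lower. The 1331 became 519 without naive wild-type library a, and the 56.3% higher became 39.9% with size factors and 38.9% and 48.9% without naive wild-type library a or b. Imprinted genes rose (5 of 12 up and 2 down, 10 adjusted over the list alone, median 0.49, camera adjusted p = 5.52e-05 on 5 genes), including Sgce (3.52), Mest (2.70) and Dlk1 (2.47), and the untested Peg10 was higher by 4.09. Germline genes rose (5 of 15, 8 adjusted over the list alone, median 1.04, adjusted p = 0.001), but 1 without naive wild-type library a, and the RNA helicase Ddx4 rose by 2.38. Mesendoderm genes had 1 of 9 up and 1 down, with Eomes at 1.49, and a median of 0.15 that was just under 0 with size factors. Trophoblast genes had a median of 0.94 (2 of 9 up and 1 down, 7 adjusted over the list alone), with Krt18 at 2.32. Primitive endoderm genes had 2 of 10 up and 1 down (camera adjusted p = 0.083). Hox genes had a median of 0.68, with 2 of 20 up (camera adjusted p = 0.288). Wnt genes had 3 of 12 up and 3 down (6 adjusted over the list alone). The 3 down became at most 1 without naive catalytic-dead library a, b or c or naive wild-type library a or b. Dkk1 rose by 3.59. Naive genes had a median of -0.21, with the untested Tcl1 lower by -2.13, and 2-cell-like genes one of -0.31. Formative genes had 1 up and 1 down of 14, with the untested Otx2 higher by 2.44. FGF and ERK genes had 2 of 12 up and 1 down (4 adjusted over the list alone), with Spry2 at -0.84. Fibroblast genes had 1 of 8 up and 1 down (median 1.21, camera adjusted p = 0.568). Neuroectoderm genes had 1 of 11 up and the tubulin Tubb3 (-1.12) down.

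In formative catalytic-dead cells mesendoderm genes were low. Eomes fell by 2.49 (SE 0.32, adjusted p = 5.66e-06), from 21.1 to 3.76 CPM, Evx1 by 3.27, the primitive streak factor T by 2.61, Wnt3 by 2.28 and Sp5 by 2.02, while the organiser gene Gsc did not pass (0.03, adjusted p = 0.979). Of 9 tested mesendoderm genes 6 fell (7 adjusted over the list alone, median -2.03, camera adjusted p = 5.64e-13). Formative floxed cells, set against the same wild-type libraries, had a median of -1.68, so the low values are not particular to the catalytic-dead line. Over the transition the list medians were 1.63 in wild-type, -0.38 in floxed, -0.91 in knockout and -1.14 in catalytic-dead cells. Il10, a cytokine with 8 counts in the lower group, rose by 5.05 (SE 0.44), and the homeobox factor Gbx2 by 2.88 (SE 0.25, adjusted p = 1.37e-07). Kcnj3, a potassium channel, fell by 3.62 (SE 0.31) and Ppp4r4 by 3.53. Of 11370 tested genes 554 rose and 396 fell, with 101 untested at least 2-fold higher and 69 lower. The 950 became 562 without formative wild-type library a, and the 58.3% higher became 47.7% with size factors. Of 9 tested 2-cell-like genes 4 fell (6 adjusted over the list alone, median -0.87, adjusted p = 1.69e-05), with Tcstv3 at -1.79, but 2, 1 and 2 did without catalytic-dead libraries a, b and c. Against the same wild-type libraries this list had a median of -4.12 in formative floxed cells. The imprinted list was higher with camera on 5 genes (adjusted p = 0.0481, with an estimated correlation 0.104, and 0.0794 without formative wild-type library c). Its median was 0.145, with 3 of 9 tested genes up and 1 down (5 adjusted over the list alone), among them Sgce at 2.56, Mest at 2.20 and Cdkn1c at -1.90. Germline genes rose (5 of 15 up and 1 down, 7 adjusted over the list alone, adjusted p = 0.0481, with an estimated correlation 0.113), a call lost without catalytic-dead library a (0.131) or formative wild-type library a (0.0597), b (0.0535) or c (0.0663). Both calls were lost with size factors (adjusted p = 0.0553). The Wnt list had 2 of 12 down, with the feedback gene Axin2 at -2.32. Formative genes had a median of -0.14, with the untested signal Wnt8a lower by -3.81, and naive genes a median of -0.10 and a mean of 0.16, with Gbx2 the 1 of 11 past the threshold. Fibroblast genes had a median of 0.84, with 2 of 7 up (4 adjusted over the list alone, camera adjusted p = 0.0576), with Col1a2 at 2.47 and Dcn at 2.41. Neuroectoderm genes had 3 of 10 up, with Sox1 at 1.66, a median of -0.12 and a mean of 0.03. Hox genes had 1 of 20 up, Hoxa5 (3.10), and 1 down. FGF and ERK genes had 1 of 7 up, Phlda1 (1.03), and 1 down, Egr1 (-1.61).

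**Figure D2:**
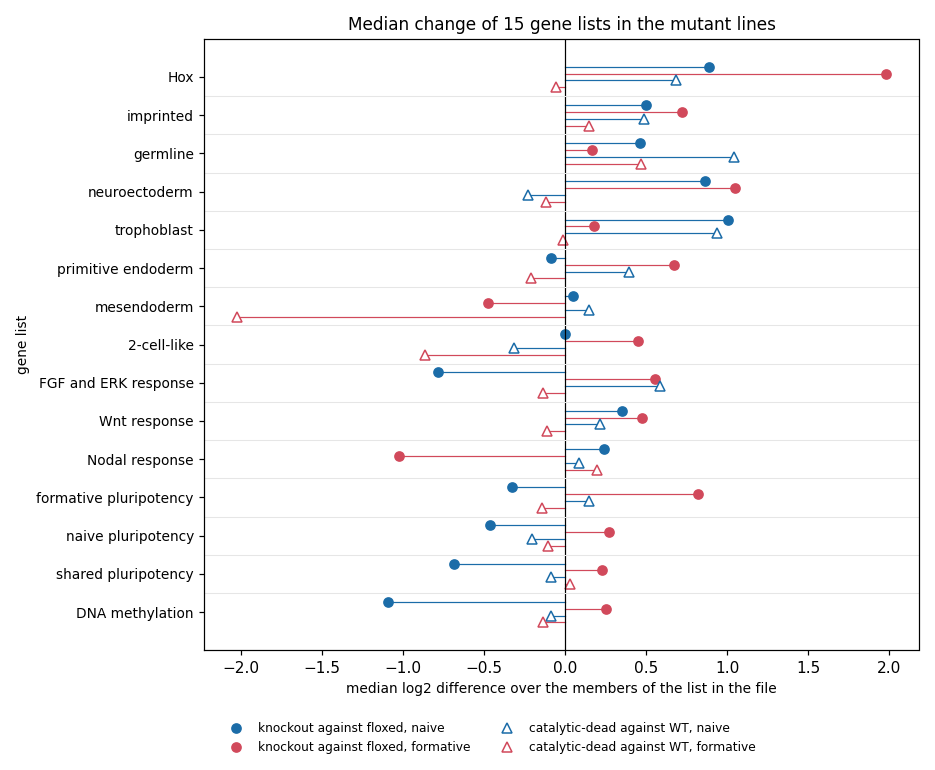
Median log2 difference of 15 gene lists in knockout against floxed cells and in catalytic-dead against wild-type cells, in naive and formative states (markers), with 0 as no difference. The Hox list stood at 0.89 and 1.98 in naive and formative knockout cells, and the mesendoderm list at -2.03 in formative catalytic-dead cells; with size factors the naive catalytic-dead medians shifted by -0.15, which turned the formative pluripotency, mesendoderm and Nodal lists to just under 0, as the shared pluripotency list did in formative catalytic-dead cells.

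Knockout and catalytic-dead effects, from comparisons without a library in common, overlapped more than independent calls would in both shared directions. In formative cells so did 1 of the opposite directions. The calls are not independent, because the model takes 1 variance per gene from all 8 groups. Genes of low spread are called more readily in every comparison, which raises overlaps in the same and in opposite directions. The expected counts and exact p values leave this out, so they do not measure chance. By the lines' names the knockout effect is loss of MLL4 where MLL3 is already lost, while the catalytic-dead effect alters both proteins. The overlaps and differences therefore do not set loss of both proteins against loss of both activities. In naive cells 172 genes were higher in both (50.0 expected, one-sided Fisher's exact p = 1.1e-51) and 196 lower in both (41.9 expected, p = 1.1e-86), while 59 moved in opposite directions (93.9 expected). Without naive wild-type library a the 368 shared genes became 173. Dab2 (3.30 and 3.84), Dlk1 (2.75 and 2.47) and Oas1a (-3.33 and -3.92) are examples for knockout and catalytic-dead cells. In formative cells 97 were higher in both (52.5 expected, exact p = 9.6e-10) and 67 lower in both (24.4 expected, exact p = 1.7e-14), while 108 were opposite (71.8 expected). Of the opposite genes 62 were lower in knockout and higher in catalytic-dead cells (33.4 expected, exact p = 1.4e-06), and 46 were higher in knockout and lower in catalytic-dead cells, which did not pass (38.4 expected, exact p = 0.11). Across genes, which are not independent, r was 0.294 in naive and 0.039 in formative cells, and Spearman's rho was 0.247 and -0.006. Between states, 301 genes were higher (80.3 expected, exact p = 1.1e-108) and 139 lower in both knockout comparisons, and 125 higher (28.9 expected, p = 7.7e-48) and 44 lower in both catalytic-dead ones. The 169 catalytic-dead genes became 71 without naive wild-type library a. The knockout effect differed from the catalytic-dead effect for 649 genes in naive cells (217 up, 432 down) and 1384 in formative cells (721 up, 663 down). The 649 became 372 without naive wild-type library a and 980 without naive floxed library b, and their 33.4% higher became 48.0% with size factors. In formative cells the Hox (adjusted p = 4.29e-05) and FGF and ERK lists (0.000273) were higher in the knockout than in the catalytic-dead effect, with 11 of 20 tested Hox genes up and 1 down (14 adjusted over the list alone). The mesendoderm list was too (0.00356). The knockout effect started from formative floxed cells, where the medians against wild type were already -0.57 for Hox, -0.31 for FGF and ERK and -1.68 for mesendoderm genes.

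The floxed line also differed from wild type. Of 2-cell-like genes, expressed in early embryos and rare cultured cells, all 9 tested fell in formative floxed cells (9 adjusted over the list alone, median -4.12, or -4.24 with the floor, camera adjusted p = 2.5e-20). Zscan4c fell there from 11.7 to 0.392 CPM, by 4.90 log2 (SE 0.50, adjusted p = 2.04e-07), and in naive cells by 3.41 (-2.63 without naive floxed library c), a call lost with the groups of the contrast alone. In naive cells 5 of 9 of the list fell (6 adjusted over the list alone, median -2.82, or -2.99 with the floor, adjusted p = 5.2e-09). In naive cells 239 of 12293 tested genes were higher and 391 lower, with Ly6a at -4.46 (SE 0.30) and the cell death gene Pmaip1 at 2.65. Fewer genes passed without naive wild-type library a, and far fewer with the groups of the contrast alone, as given below. In formative cells 453 of 11083 were higher and 602 lower, which became 686 in all without formative wild-type library a. Gc, a vitamin D carrier, rose there by 4.44 and Psors1c2 fell by 3.52. Of 9 formative mesendoderm genes 6 fell (7 adjusted over the list alone, median -1.68, adjusted p = 3.76e-09), with Sp5 at -2.33, Eomes at -2.18 and Wnt3 at -1.58. Germline genes fell with camera (5 of 15, 7 adjusted over the list alone, adjusted p = 0.0103, with an estimated correlation 0.0548), where the 5 became 2 without formative floxed library b, 3 without c, 2 without formative wild-type library a and 3 without b. The Hox list was lower with camera (1 of 20 tested genes fell, adjusted p = 0.028, with an estimated correlation 0.0548), a call lost without formative floxed library a (0.0993) or formative wild-type library b (0.051). The FGF and ERK list was lower with camera (2 of 7 tested genes fell, adjusted p = 0.0441, with an estimated correlation 0.0722), a call lost without formative floxed library a (0.0993) or c (0.0895) or formative wild-type library a (0.05) or c (0.0895). Gadd45g fell by 1.98 and the imprinted Dlk1 by 1.28. The formative pluripotency list had a median of -0.73, with 7 of 17 members at least 2-fold lower, including Lef1 (-1.33), and the naive list a median of 0.14, with Dppa3 at 2.07.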

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

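The tests of explanations in this part were all chosen after the results they weigh had been seen, and so were the weights in the model.

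The formative knockout column averaged 4 libraries, 1 of which also entered the formative catalytic-dead column. A mislabelled knockout sample is argued against by the library's correlations, which were at least 0.883 with the other formative catalytic-dead libraries and at most 0.753 with formative knockout libraries. Whole counts were found for 99.9% of genes with up to 100 counts when 4 libraries were assumed, so the library did enter the average. This cannot tell an averaging slip from an intended inclusion. Why the naive wild-type column averaged 2 libraries was not tested. With the column as deposited, 1098 in place of 1877 genes passed in formative knockout cells, 1047 of them shared.

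Naive floxed cells differed from naive wild-type cells at 630 genes, although MLL4 is not deleted in either line by name. Far fewer passed with the groups of the contrast alone, as given below, so the shares here rest on the full model. Annotated pseudogenes do not make up the calls, since 7.46% of called genes and 7.27% of tested genes were annotated pseudogenes (two-sided Fisher's exact p = 0.81). A difference carried by the floxed and knockout lines together may contribute: 77.6% of the called genes had the same sign in knockout minus catalytic-dead cells, against 54.8% of all tested genes. In formative cells these shares were 58.9% and 49.5%. Loss of MLL3 and other differences between the lines both remain open, because the floxed line carries both, and reads shared between paralogous genes were not tested.

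Genes repressed in the wild-type transition were already lower in naive knockout than naive floxed cells, with a median of -0.66 over 856 genes, and induced genes had a median of 0.18. Normalization as the whole cause is argued against by the median of -0.63 with size factors. Any 1 library is argued against by medians of -0.68 to -0.61 when each was left out. Formative cells mixed into the naive knockout cultures were given the values of formative floxed cells. They would need a share of 70.8% at the median of 493 repressed genes, with a wide spread between genes. The 59 abundant induced genes implied a median of -0.861% and a 90th percentile of 14.3%. This argues against cells with formative floxed values as the whole cause. Formative cells in a knockout culture would be knockout cells, and the share of those was not computed. A large share would bring induced genes of the naive culture near formative knockout levels. Over the knockout transition the 1720 induced genes still had a median of 1.28, and the formative list one of 2.71. In naive knockout against floxed cells the formative list had a median of -0.33, and 259 induced genes were higher and 64 lower. These values argue against formative knockout cells as the whole cause, and a smaller share remains open. What lowers the repressed genes was not tested.

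The difference of transitions between knockout and floxed cells passed for 829 genes, and 2 of 100 drawn splits gave as many, the real one included. The other, with 2324 genes, exchanged the whole groups of the lines in 1 state, so it summed their effects. The remaining splits mixed libraries of at least 1 pair of groups, which raises the spread, so the share does not measure chance. Enox1, Spry4 and Sgk2 differed by 6.25, 5.63 and 4.78, and Hhip, Trim67, Dkk1 and B3gnt3 by -5.10, -4.89, -4.25 and -4.23. Without formative knockout library c Hhip stood at -4.34 and B3gnt3 at -5.21, and without naive floxed library c Dkk1 stood at -3.52. The FGF and ERK list kept an adjusted p of 0.0244 with an estimated correlation.

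The difference of transitions between catalytic-dead and wild-type cells passed for 331 genes, 164 without naive wild-type library a and 219 without naive catalytic-dead library c. The difference was positive for Il10 (5.06), Apol6 (4.13), Ly6a (3.98) and Oas1a (3.65). It was negative for Runx3 (-4.37), Eomes (-3.98), Psors1c2 (-3.72) and Irx3 (-3.62). A positive difference need not be a rise over the catalytic-dead transition. Ly6a and Oas1a fell in the wild-type transition, and Apol6, Ly6a and Oas1a were already far lower in naive catalytic-dead than wild-type cells, as given above. Without naive wild-type library b Psors1c2 stood at -3.13 and Irx3 at -2.56. The Oas1a call was lost with a prior count of 0.5 and with voom weights. The mesendoderm list was lower (adjusted p = 0.000194 with an estimated correlation), with 3 of 9 tested genes down and 1 without naive wild-type library a. The mesendoderm median over the transition was negative in the floxed line too (-0.38), against 1.63 in wild-type cells. The primitive endoderm, trophoblast and imprinted lists were lower at 0.0492 with an estimated correlation. With the preset correlation the primitive endoderm and trophoblast calls were lost without naive wild-type library a (0.0827 and 0.143), and the imprinted call without naive wild-type library b (0.0539).

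The knockout and catalytic-dead effects differed for 649 genes in naive cells, 372 without naive wild-type library a and 980 without naive floxed library b. The knockout effect is that of MLL4 loss in cells already without MLL3 by name, while the catalytic-dead effect alters both proteins. Tex13b (6.09), Nlrp4c (5.98), AI662270 (5.75) and Ly6a (4.11) were higher in the knockout effect, and Porcn (-5.12), Gc (-4.95), Calml4 (-4.83) and Eomes (-4.34) lower. The Ly6a difference says little about the knockout. Ly6a was already far lower in naive floxed than wild-type cells, about as low as in naive catalytic-dead cells, as given above. Gc stood at -4.24 without naive knockout library b, and its call was lost without naive wild-type library a (-4.91). In formative cells 1384 genes differed, a number reached by 2 of 100 drawn splits, of which the real split was 1 and the other, with 1408 genes, exchanged whole groups of 1 pair. The remaining splits mixed libraries of at least 1 pair, which raises the spread, so this share does not measure chance either. Kcnj3 (6.06), Magel2 (5.98), Ccn4 (5.68) and Tex13b (5.41) were higher, and Dcn (-4.83), Sycp3 (-3.87) and Smc1b (-3.71) lower. Ccn4 stood at 5.08 without formative floxed library b, Tex13b at 6.09 without formative wild-type library c, and Sycp3 at -3.24 without formative wild-type library b. The Ccn4 and Tex13b calls were lost with the knockout column as deposited, at 4.45 each. With an estimated correlation the 2-cell-like (0.0379), mesendoderm (0.0202), FGF and ERK (0.00523) and Hox lists (0.0039) kept adjusted p under the threshold. The Hox and FGF and ERK lists also started lower in formative floxed than wild-type cells, with medians of -0.57 and -0.31. The 2-cell-like and mesendoderm differences say little about the knockout, because in formative floxed cells these lists already had medians of -4.12 and -1.68 against wild type, and 3 of the 9 2-cell-like genes had no more than 3 counts in both floxed and knockout cells.

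With 3 against 3 libraries there are 10 splits, too few for a share under 0.05. The real splits gave 3675 genes for the floxed, 2819 for the knockout and 3316 for the catalytic-dead transition, 1961 and 1877 for naive and formative knockout cells, 950 for formative catalytic-dead and 1055 for formative floxed cells, and the highest other split gave 0 each time by limma at the adjusted threshold. Every other split mixed libraries of both groups, which puts their difference into the spread, so these counts do not measure chance.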

How the results depend on the processing

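Fits with genes recovered in every library, the column as deposited, a prior count of 0.5, voom weights or no weights were chosen after the results had been seen. No paired analysis was possible because the deposited columns carry no replicate numbers, so a replicate block could not be fitted. A count model with its own size factors or TMM could not be fitted to the deposited log2 means. It was not run on the recovered counts, which leave out abundant genes. Of 430 alternatives for 23 counts, 398 stayed within 1.5 times and 32 moved further. The side with more genes turned for 3 counts. The share higher in naive catalytic-dead cells went from 56.3% to 39.9% with size factors and to 38.9% and 48.9% without naive wild-type library a or b, and in formative catalytic-dead cells from 58.3% to 47.7% with size factors. For the difference of effects in formative cells it went from 52.1% to 46.2% with the knockout column as deposited and to 49.0% without formative catalytic-dead library a. The cause was not tested. No result for a named gene that passed in the model or the alternative changed sign. Counts held within 1.5 times in each transition and in naive knockout cells, with ranges of 2542 to 3744, 3197 to 3312, 2210 to 2593 and 2546 to 2981 for the wild-type, floxed, knockout and catalytic-dead transitions and 1494 to 1879 in naive knockout cells when 1 library was left out.

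Counts in naive catalytic-dead cells (1331) ran from 519 without naive wild-type library a to 1110 without library b, and were 631 with the groups of the contrast alone, 829 with genes recovered in every library and 803 with voom weights, both of which test fewer genes. Formative catalytic-dead cells (950) gave 562 to 785 with 1 library left out and 607 without weights. Naive floxed cells (630) gave 322 to 704, and 113 with the groups of the contrast alone, and formative floxed cells (1055) gave 686 to 898, and 679 with those groups alone. The differences gave 164 to 340 and 198 with voom weights for the catalytic-dead transition (331), 372 to 980 for naive effects (649) and, with the knockout column as deposited, 446 for formative effects (1384) and 1098 for formative knockout cells (1877). That column includes a catalytic-dead library, which raises the spread and shrinks the difference. Fewer libraries explain part of the lower counts; the cause was not tested further.

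Shared knockout and catalytic-dead genes were 173 to 351 in naive (368) and 112 to 163 in formative cells (164) with 1 library left out, and 170 and 107 with the groups of the contrast alone. Genes shared between states were 249 for the knockout with the column as deposited (440), and 71 to 144 and 80 with the groups alone for the catalytic-dead line (169). Genes with a smaller change were 112 of the induced and 85 of the repressed set for the knockout when sets needed a log2 change of 2, which holds fewer genes (169 and 184). For the catalytic-dead line the repressed count (45) was 28 to 48, 27 with voom weights and 18 with the smaller set, and the induced count (56) was 16 to 64 and 35. Of 196 list tests 47 passed, 42 with size factors and 30 with an estimated correlation; for these the cause was not tested.

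Of 846 results for named genes, 681 passed, of which 491 did so under every alternative and 190 were lost under at least 1, 160 of them with 1 library left out. The groups of the contrast alone lost 68, the knockout column as deposited 45, no weights 35, a prior count of 0.5 27, size factors 21 and voom weights 17, and 31 results were gained under some alternative. In data simulated at the depths of these libraries 57.1% of 2-fold and 11.4% of 1.5-fold changes were called, and neither depth nor the spread between replicates was varied. Only the naive knockout comparison was scored, with 200 changed genes, where the real one called 1961. The adjusted threshold depends on the share of changed genes, so these rates need not hold for the real comparisons.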

Other observations

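The genes of the last paragraph were chosen after their values were seen, and the other values belong to lists fixed in advance. Of 5 tested p53 targets in naive knockout cells the death receptor Fas (3.05) and the kinase Plk2 (1.24) rose and Pmaip1 fell by 2.32 (3 adjusted over the list alone, median 0.60), and in formative knockout cells 2 of 3 rose (2 adjusted over the list alone, median 0.75), with Fas at 3.02, or 2.32 without formative floxed library b. The medians were 0.30 in naive and -0.30 in formative catalytic-dead cells. Glycolysis genes had medians of -0.36 in naive knockout, -0.23 in formative knockout, -0.33 in naive catalytic-dead and 0.23 in formative catalytic-dead cells, and the aldolase Aldoc fell in the first 3 of these (-1.38, -1.72 and -1.28). Interferon response genes had a median of 0.37 and a mean of -0.42 in naive knockout cells, where Bst2 rose by 1.37 and Oas1a fell by 3.33 (2 of 6 adjusted over the list alone). The medians were 0.36, -0.56 and 0.19 in formative knockout, naive catalytic-dead and formative catalytic-dead cells, and the sensor Ddx58 fell by 1.42 in naive catalytic-dead cells.

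General pluripotency genes had medians of -0.69 in naive and 0.23 in formative knockout cells, -0.09 in naive catalytic-dead and 0.03 in formative catalytic-dead cells, the last turning to -0.05 with size factors. The list of H3K4 methyltransferase complexes, which includes Kmt2c and Kmt2d, had medians of -0.09, 0.21, -0.03 and -0.30 in the same order, and Ncoa6, a subunit shared by the MLL3 and MLL4 complexes, rose by 0.86 in formative knockout cells. Other chromatin regulators had medians of -0.13, 0.21, 0.10 (-0.05 with size factors) and -0.11. DNA methylation genes had medians of -1.09, 0.25, -0.09 and -0.14, with a mean of -0.04 in formative knockout cells, where the dioxygenase Tet3 rose by 1.28 and the untested Dnmt3l was lower by -1.55. LIF and STAT3 genes had medians of 0.27, 0.53, -0.02 and -0.18. Nodal genes had medians of 0.24, -1.03, 0.09 (-0.07 with size factors, mean -0.15) and 0.20, with the antagonist Lefty2 falling by 1.99 in naive catalytic-dead cells. Oxidative phosphorylation had medians of 0.16, -0.04, 0.03 (-0.12 with size factors) and 0.00, cholesterol biosynthesis -0.06, -0.02, -0.16 and -0.26, and proliferation 0.15, -0.04, 0.19 and 0.15. The Y-linked and Xist list had medians of 0.59, 0.08, 0.18 and 0.18, and its member Eif2s3y rose by 1.15 in naive knockout cells.

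In formative floxed cells the untested ribosomal protein gene Rpl34 had values higher by 5.28 than in wild-type cells, and by 4.78 in naive cells, and the pseudogene Rps3a3 was lower by -4.35 and -4.72. These genes have processed copies with near identical sequence, and they were chosen after their values were seen.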
